A study of Homo sapiens with 30 samples.

How the data were processed

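Bulk RNA sequencing was made from natural killer (NK) cells of 4 organ donors, sorted as CD56bright CD16-negative and CD56dim CD16-positive cells from blood, bone marrow, spleen, lung and lung lymph node. Per the labels, tissues were kept in cold saline and reached the laboratory within hours, spleen and lung were digested with enzymes and mechanically, and blood cells were taken by density centrifugation. The handling of bone marrow and lymph node was not specified. RNA was purified on columns and libraries were made with a poly-A selecting kit.

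The first deposited table held a raw count per gene symbol and library, as whole numbers with differing library totals. The second table held the authors' normalized values, which lay between 7.75 and 18.64 and had a median correlation of 0.91 with log2 CPM (counts scaled to a common library total) of the first table. The authors' values were therefore read as being on a log2-like scale and used without a further logarithm, although their transformation was not stated. The mean SD of donor coefficients was 0.058 in these values and 0.976 in log2 CPM, so donor differences were nearly absent from the second table. The submitters' processing notes named STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the genome build hg38. Their roles and settings were not stated, and the gene annotation was not given in the sources used here, so no coordinates are given and genes are identified by symbol.

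The count table had 11943 symbols. XIST and Y-linked genes, 8 symbols, were left out before all tests. A further 282 symbols were at 0 in every library of donor 4 and were treated as missing there and left out. Of these, 261, or 92.6%, were absent from the gene name table at hand, against 2.4% of the other symbols, and 207 had a median above 5 CPM in the other libraries. This left 11653 genes. The low-count filter (filterByExpr with a minimum count of 10) removed 0 of them, so the alternative of no filter changed nothing and tested nothing.

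Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling factors and quasi-likelihood F tests in 1 fit of all 30 libraries with a mean for each of the 10 tissue and subset groups (20 residual degrees of freedom). All groups thus shared the estimate of the spread. Donors were not in this model. Donors 1 and 2 gave libraries of all 5 tissues, donor 3 of blood and spleen, and donor 4 of bone marrow, lung and lymph node. A fit with donor as a block, with 17 residual degrees of freedom, was an alternative. Library numbers are donor codes and pair libraries across groups. The deviations of libraries from their group means had a median correlation of 0.20 across genes in 111 pairs from 1 donor, and of -0.06 in 294 pairs from different donors. Contrasts compared CD56dim with CD56bright over the mean of the 5 tissues and in each tissue, and each other tissue with blood within each subset. Tests with several degrees of freedom asked whether a gene differed between any tissues within a subset, and whether its subset difference depended on tissue. P-values were two-sided and Benjamini-Hochberg adjusted over the 11653 genes within a comparison, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute change divided by the square root of F. Levels are log2 CPM with a prior count of 1, as mean and SD over 3 libraries unless another n is given.

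Where every library of a group was at 0 for a gene, the fold is a lower bound against a floor of 3 counts per library, and no fitted fold is given. Floors cover counting error only, since reads were not tagged with molecular identifiers. Symbols in families of near-identical sequence (HSPA1A and HSPA1B, CCL4 and CCL4L2, XCL1 and XCL2, killer-cell immunoglobulin-like receptors, surfactant and tryptase genes) can share reads, so their values are uncertain between members. Some genes of the lists are not reported here by name, though list tests and counts include them.

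The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Over the 5 tissues the rule took up to 12 genes higher and 12 lower with the largest fold change among those with an adjusted p under the threshold, a mean of at least 3 log2 CPM and the same sign in all 15 pairs of libraries. For a tissue against blood it took 6 and 6, and for the subsets within a tissue 3 and 3, among genes whose 3 and 3 libraries did not overlap, which chance gives for 10% of genes. For the dependence on tissue it took the 10 smallest p. It also took up to 4 called members of each list and, always, FCGR3A (CD16) and NCAM1 (CD56). Cells were sorted on these last proteins, so their transcripts are a check of the sort, not a result. Variable immunoglobulin and receptor segments and a fixed set of genes whose presence differs between people were not named.

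The 25 gene lists were tested in 14 contrasts with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, which ranks a list against all other genes, with adjustment over 350 tests. A correlation estimated per list and the rotation test fry were alternatives. Members of lists absent from the table, such as T cell receptor and immunoglobulin constant genes, RIPOR2 and several chemokine receptors, were not measured. The other alternatives were median-ratio (RLE) scaling, DESeq2 1.42.0, limma-trend on the authors' normalized values, fits of only the groups compared, and leaving out each library or donor in turn. 4 alternatives were chosen after seeing the data: leaving out 3 sparse libraries together, spleen in place of blood as reference, keeping the 282 symbols, and limma-voom with sample weights. RLE moved the median log2 change of all genes by less than 0.1 in every contrast.

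The edgeR test was tested on simulated data of the same size. It recovered 52.2%, 80.6% and 90.9% of genes changed 2-fold, 4-fold and 8-fold for the subset comparison over tissues, with 9 of 158 calls on unchanged genes. For lung against blood in CD56dim cells it recovered 1.5%, 22.4% and 47%, so that most 2-fold and 4-fold changes in comparisons of 3 with 3 libraries would be missed. For the subsets in lung it recovered 0%, 19.4% and 53%, and for the dependence on tissue 0%, 3% and 19.7%. DESeq2 put 44 of 205 and 32 of 119 calls on unchanged genes in the first pair of these comparisons, so its larger counts are given as alternatives only. Camera called a list of 20 genes with 10 raised in each of the first 3 comparisons, and 0, 0 and 1 of 100 unchanged lists. The simulated genes were drawn independently of each other, without donor effects or sparse libraries. The simulation therefore cannot show how often the tests call unchanged genes or lists when genes or libraries are correlated.

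Library totals ran from 9945156 to 40719690 counts (median 21098240.5). The libraries of donor 4 had the highest totals, from 28922637 to 40719690, against at most 25010559 in any other library. Donor 4 was also the donor with the 282 symbols at 0. Whether its libraries were processed apart was not stated. It gave no blood or spleen, so such a difference would be partly confounded with comparisons of bone marrow, lung and lymph node with blood or spleen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.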

Results

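The series measured the transcriptomes of 2 subsets of human NK cells, innate lymphocytes that kill infected or transformed cells, in blood and in 4 other tissues. CD56bright cells are regarded as the less mature, cytokine-producing subset and CD56dim cells as the mature cytotoxic subset. The 30 libraries fell into 10 groups, 5 tissues by 2 subsets, with 3 libraries each from 3 of 4 donors. Blood and spleen came from donors 1, 2 and 3, and bone marrow, lung and lung lymph node from donors 1, 2 and 4. The comparisons address how the subsets differ from each other in each site and how each subset differs between tissue and blood.

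Total counts per library ran from 9945156 to 40719690. In 3 libraries many genes were at 0: blood CD56bright library 1 had 1787 such genes of 11653 at a total of 14492285 counts, blood CD56bright library 2 had 1729 at 9945156, and bone marrow CD56bright library 4 had 1543 at 31844887. The other 27 libraries had 21 to 642, the highest in blood CD56bright library 3. Among 5842 genes with a median of at least 30 CPM, the 3 libraries had 583, 241 and 143 below 3 CPM, against at most 27 in any other library. These libraries are called sparse here, a group defined from the data and not by the study. They make up 2 of the 3 blood CD56bright libraries, the reference of every CD56bright comparison with blood. A fit without them has 1 blood CD56bright library, with a spread taken from the other groups. Calls kept or lost in that fit are therefore weak evidence for comparisons with blood CD56bright cells.

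**Figure D1:**
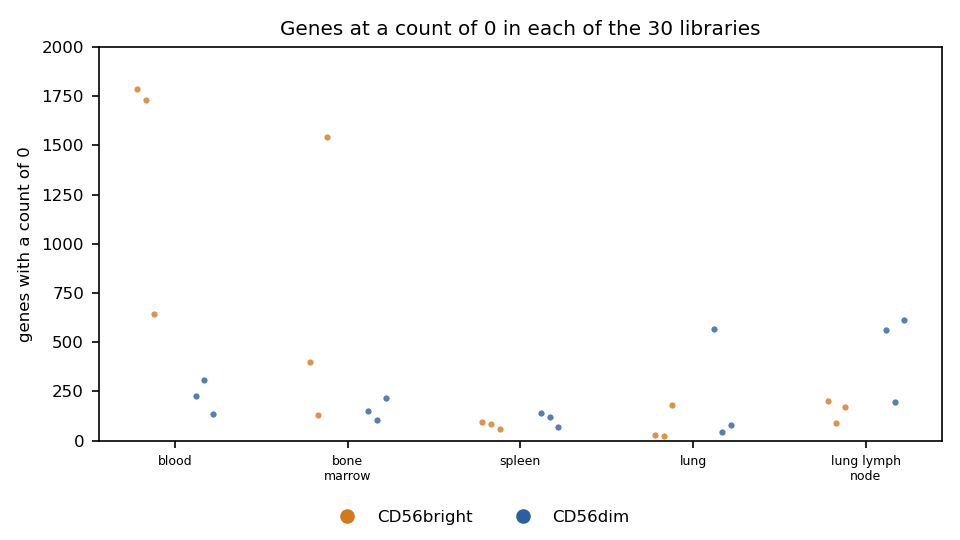
Number of genes with a count of 0 (y axis, of 11653 genes) in each library (points), by tissue (x axis) and subset (colour). The 3 sparse libraries lie at 1543 to 1787 genes and the other 27 at 21 to 642.

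Tissue accounted for 26.2% of the variance of log2 CPM over all genes, subset for 10%, donor for 15.2%, the interaction of subset and tissue for 12.5% and the residual for 35.6%. These shares were not adjusted for degrees of freedom, of which tissue, donor and the interaction have more than subset. Noise alone gives such a factor a larger share, so the shares do not rank the factors. The first 3 principal components held 23.8%, 12.2% and 11.4%, and the sparse libraries had the 3 lowest scores on the first.

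Over the 5 tissues, CD56dim cells had far more transcript of the effector and migration genes of mature NK cells. FGFBP2, a protein secreted by cytotoxic lymphocytes, was at 8.62 ± 0.90 log2 CPM in CD56dim and 1.62 ± 2.61 in CD56bright libraries (SD, n = 15 each), a fitted 78.7-fold rise (log2 6.30 ± 0.59 SE, adjusted p = 9.93e-08). The prostaglandin synthase PTGDS rose 84.9-fold (log2 6.41 ± 0.68 SE), the serine protease PRSS23 73.1-fold (6.19 ± 0.71) and CX3CR1, the fractalkine receptor of circulating effector cells, 60.9-fold (5.93 ± 0.72). CD56bright cells had more IL7R, the receptor chain for interleukin-7, which was 15.4-fold lower in CD56dim cells (log2 -3.95 ± 0.33 SE, adjusted p = 1.67e-08). They also had more CXCR6, a chemokine receptor linked to tissue retention (22.6-fold lower in CD56dim, -4.50 ± 0.43). GZMK, a granzyme, was 12.4-fold lower in CD56dim cells (-3.63 ± 0.35). The naming rule required the same direction in 15 of 15 pairs of libraries of 1 donor and tissue. That sameness in these 7 genes is therefore no further support for them. The 15 libraries of a subset, here and below, are several tissues of each of 4 donors. The fit took them as independent and did not use the pairing, so its SEs and p-values do not rest on donors as replicates.

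Of the other genes picked by size and sameness of sign, MYOM2 (46.4-fold), AKR1C3 (16.9-fold), and CXCR2, a neutrophil-type chemokine receptor (14.7-fold), rose in CD56dim cells. ITM2C fell 17.3-fold, SPRY1, an inhibitor of growth factor signalling, 11.1-fold, XCL1, a chemokine for cross-presenting dendritic cells, 8.95-fold, and the actin-capping CAPG 7.11-fold. Of the 16 listed markers of mature CD56dim cells, 15 rose and none fell (16 when adjusted over the list alone, camera adjusted p = 4.51e-37). Of 20 CD56bright markers 18 fell (18 when adjusted over the list alone, adjusted p = 1.65e-35). Among them S1PR5, the sphingosine receptor for exit from tissue, rose 6.17-fold (2.63 ± 0.32), and KIT, the stem cell factor receptor, fell 26.5-fold (-4.73 ± 0.47). These 2 lists hold genes already known to mark the subsets, and each holds a sorting marker (FCGR3A and NCAM1).

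The cytotoxic granule list rose: 9 of 18 members were higher in CD56dim cells (11 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.41e-09). PRF1, perforin, rose 3.6-fold (1.85 ± 0.23 SE), NKG7 3.30-fold, and the granule protease activator CTSC 2.01-fold. Of 17 genes of tissue egress and circulation 13 rose and 2 fell (14 and 3 when adjusted over the list alone, adjusted p = 2.06e-08). CCR7, the lymph node homing receptor, was among those that fell (18.9-fold, -4.24 ± 0.62). Of 17 tissue residence genes 6 fell (6 when adjusted over the list alone, adjusted p = 2e-06), among them the integrin ITGA1 (29.8-fold, -4.90 ± 0.78), CRTAM (3.79-fold) and RBPJ, the Notch effector (1.75-fold). Of 19 inhibitory receptors 10 rose and 3 fell (13 and 3 when adjusted over the list alone, adjusted p = 6.38e-07). All 4 of these lists stayed under the threshold with an estimated correlation, at adjusted p = 0.0362, 0.00699, 0.000618 and 0.0357.

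Activating receptors rose by camera (7 of 18 up and 2 down, 9 and 2 when adjusted over the list alone, adjusted p = 0.0204, but adjusted p = 0.153 with an estimated correlation). The 7 include FCGR3A (CD16), on whose protein the cells were sorted, so its rise is part of the sort and not a result. CD244 rose 2.30-fold and NCR3 3.20-fold. NK transcription factors fell by camera (4 of 30 up and 7 down, 6 and 10 when adjusted over the list alone, adjusted p = 0.0285, but adjusted p = 0.151 with an estimated correlation). RUNX2 was 16.2-fold lower in CD56dim cells (-4.02 ± 0.33 SE), AHR, the aryl hydrocarbon receptor, 6.96-fold lower and TOX2 15-fold lower, while ZEB2, a transcriptional repressor active in terminal effector cells, was 3.10-fold higher. Of 12 chemokine receptors 4 rose and 6 fell (4 and 6 when adjusted over the list alone, adjusted p = 0.912), and their median log2 change of -0.67 and mean of 0.21 differed in sign. The chemerin receptor CMKLR1 was at 4.80 ± 1.43 log2 CPM in CD56dim and -1.70 ± 2.72 in CD56bright libraries (SD, n = 15 each, adjusted p = 4.07e-08). Of 19 cytokines and chemokines 3 rose and 4 fell (5 and 4 when adjusted over the list alone, adjusted p = 0.512), with LTB 2.49-fold lower in CD56dim cells.

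Markers of other lymphocytes moved with the CD56bright subset. Of 9 markers of other innate lymphoid cells 5 were lower in CD56dim cells (5 when adjusted over the list alone, adjusted p = 3.24e-08, and 0.00019 with an estimated correlation). IL23R was one of them, at 3.26 ± 2.08 log2 CPM in CD56bright and -2.74 ± 2.27 in CD56dim libraries (SD, n = 15 each). Of 10 T cell markers 5 were lower (6 when adjusted over the list alone, adjusted p = 6.42e-05, but adjusted p = 0.0503 with an estimated correlation), with CD3D 7.96-fold and CD5 14.9-fold lower in CD56dim cells. CD3D was at 4.96 ± 3.10 log2 CPM in CD56bright libraries (SD, n = 15) and lower in CD56dim in 12 of 15 pairs. Immediate-early genes ranked lower in CD56dim cells by camera with 0 of 22 members called (0 when adjusted over the list alone, adjusted p = 0.0216, but adjusted p = 0.582 with an estimated correlation).

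The remaining lists did not pass camera. Interferon-stimulated genes had 1 of 25 members up (3 up and 1 down when adjusted over the list alone, adjusted p = 0.202). Heat shock genes had 0 of 16 called (adjusted p = 0.529), proliferation genes 0 of 25 (0.199), glycolysis and hypoxia 1 of 21 down (0.123), and NF-kB targets 1 of 19 down (0.0622). B cell markers had 1 of 9 down (1 up and 3 down when adjusted over the list alone, 0.385). Plasma cell markers had 1 up and 2 down of 5 (1 and 3 when adjusted over the list alone, 0.235). Monocyte and macrophage markers had 0 of 14 called (0.373), granulocyte and progenitor markers 1 up and 1 down of 11 (0.864), dendritic cell markers 1 of 4 down (0.0876), erythroid and platelet markers 0 of 8 (0.969), and epithelial, endothelial and stromal markers 2 of 15 down (0.244). Where no count is given, the count adjusted over the list alone was the same.

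In all, 1232 of 11653 genes differed between the subsets over the tissues by edgeR, 624 higher and 608 lower in CD56dim cells. CD16 transcript, FCGR3A, was 20.5-fold higher in CD56dim cells (4.36 ± 0.42 SE), and NCAM1 differed by -0.44 ± 0.24 (adjusted p = 0.31, and 0.0271 with donor as a block). The count was 2008 without blood CD56bright library 3 and 1905 without the 3 sparse libraries. Of 62 called and named genes, 61 kept the call when any 1 library was left out, and TNFSF4, an innate lymphoid marker, lost it without blood CD56bright library 3 (adjusted p = 0.00212 with it and 0.0931 without). When any 1 donor was left out 8 of the 62 lost it.

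**Figure D2:**
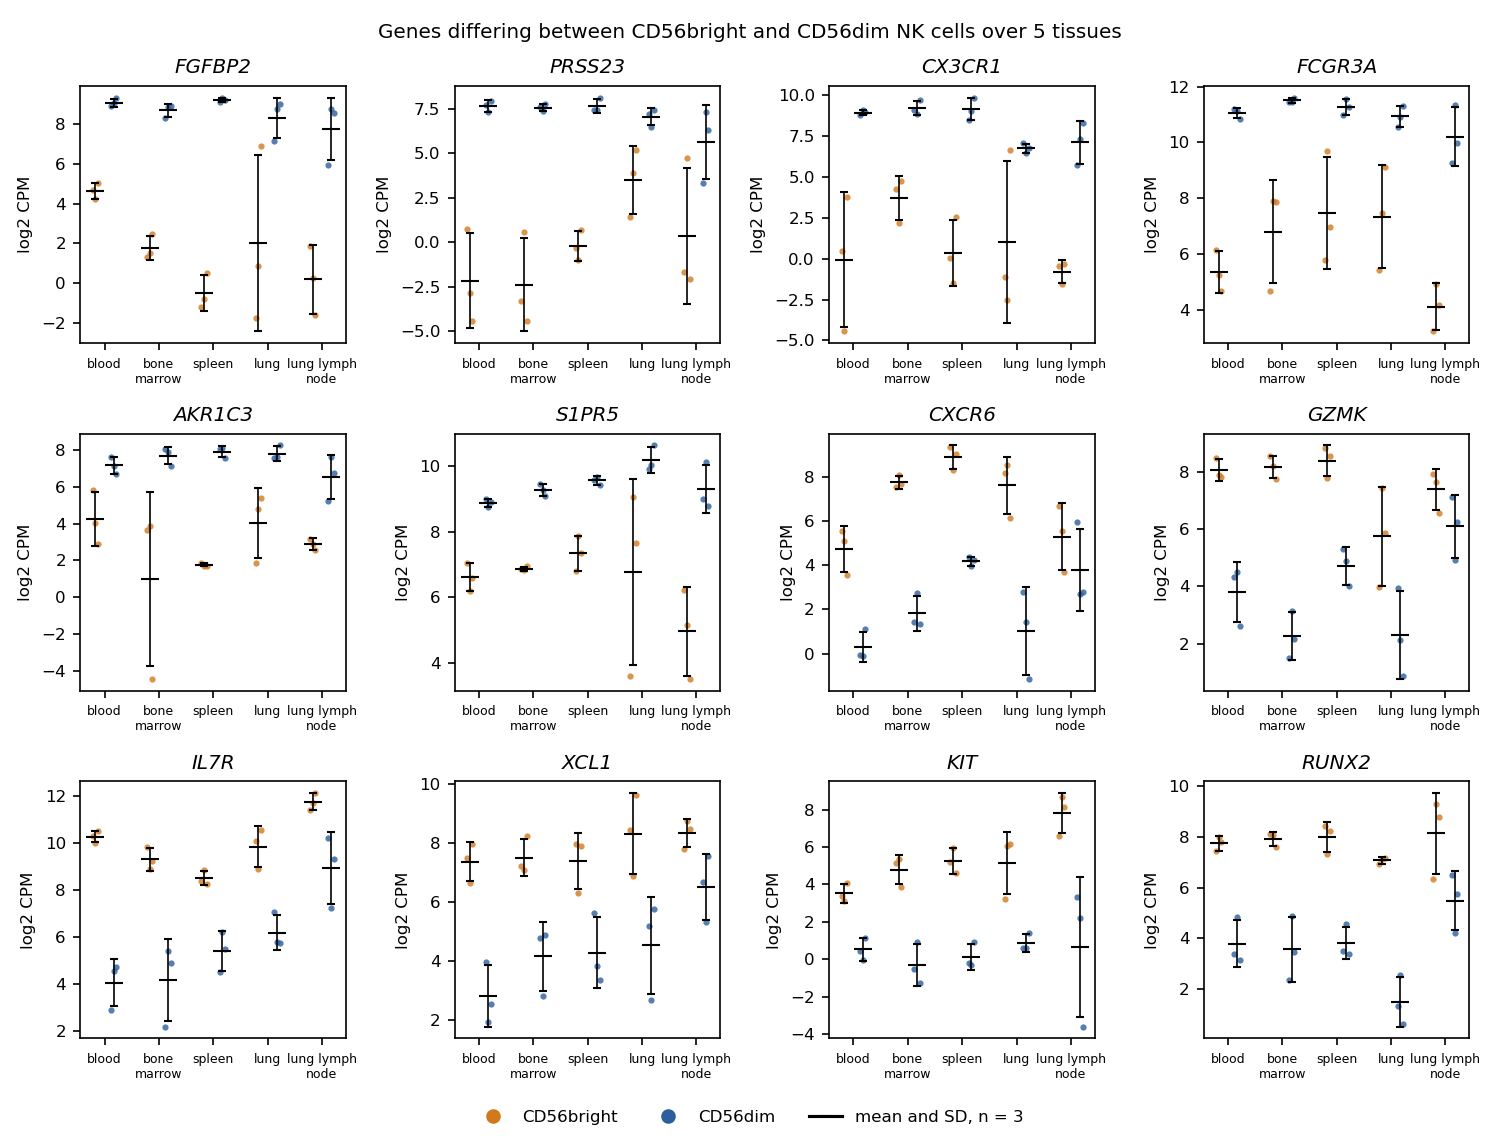
Expression of 12 genes (panels; y axis log2 CPM) by tissue (x axis) and subset (colour); points are libraries and bars mean and SD of 3. FGFBP2, PRSS23, CX3CR1, FCGR3A, AKR1C3 and S1PR5 were higher in CD56dim in 15 of 15 pairs, and CXCR6, GZMK, IL7R, XCL1 and KIT lower in 15 of 15. Except for S1PR5 and KIT, named from lists, these genes were picked for that sameness.

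Within blood, FCGR3A was 48.2-fold higher in CD56dim cells (11.06 ± 0.19 against 5.34 ± 0.75 log2 CPM, SD, n = 3) and IL7R 65.2-fold lower (log2 -6.03 ± 0.81 SE, adjusted p = 8.45e-05). IGFBP4, which binds insulin-like growth factors, was at -3.91 ± 0.92 log2 CPM in CD56dim and 6.11 ± 1.66 in CD56bright cells (SD, n = 3, adjusted p = 0.000796). CCR7 was at -2.19 ± 2.03 against 6.82 ± 0.45 (adjusted p = 0.00417). XCL1 fell 20.9-fold, GZMK 16.8-fold and RUNX2 13.6-fold, and CD244 rose 5.46-fold. PCDH1, at least 244-fold higher in CD56dim cells, and TIRAP, at least 72-fold, were at 0 in all 3 blood CD56bright libraries, 2 of them sparse. By edgeR 736 genes differed, 504 higher and 232 lower in CD56dim cells. The count was 2288 without blood CD56bright library 3, and 387, 390 and 372 without CD56dim libraries 1, 2 and 3. It was 760 without the sparse libraries, but only 278 genes were in both sets, and 3 when only these groups were fitted. By limma-voom it was 43, of which only 5 were higher in CD56dim cells, so the balance of directions turned.

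In bone marrow, GZMK was 55.2-fold lower in CD56dim cells (log2 -5.79 ± 0.88 SE, adjusted p = 0.00272) and IL7R 25.5-fold lower (-4.67 ± 0.76, adjusted p = 0.00399). PDGFRB, a growth factor receptor, was at least 912-fold higher in CD56dim cells (adjusted p = 0.00696) and at 0 in the 3 CD56bright libraries. FCGR3A was 17.6-fold higher (4.14 ± 0.93) with adjusted p = 0.0345, a call lost without any 1 of the 6 libraries (up to 0.119 without CD56bright library 1). By edgeR 74 genes differed, 30 higher and 44 lower in CD56dim cells, and 10 of the 13 called and named genes lost the call in at least 1 of the 6 fits. The count was 13, 37 and 16 without CD56dim libraries 1, 2 and 4, and 37 without CD56bright library 4. It was 149 with donor as a block, 26 when only these groups were fitted and 270 by limma-voom.

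In spleen, FGFBP2 was at 9.22 ± 0.11 log2 CPM in CD56dim and -0.49 ± 0.90 in CD56bright cells (SD, n = 3, adjusted p = 0.00216). FCGR3A differed by 2.90 ± 0.88 on the log2 scale with adjusted p = 0.221 (0.0332 with donor as a block). Its level in spleen CD56bright libraries was 7.47 ± 2.01 log2 CPM, against 5.34 ± 0.75 in blood. By edgeR 43 genes differed, 33 higher and 10 lower in CD56dim cells, and 9 of 10 called and named genes lost the call in at least 1 fit. The count was 11, 17 and 15 without CD56bright libraries 1, 2 and 3, and 21, 25 and 21 without CD56dim libraries 1, 2 and 3. It was 104 with donor as a block, 144 without the sparse libraries, 475 when only these groups were fitted and 1310 by limma-voom.

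In lung, RUNX2 was 41.3-fold lower in CD56dim cells (log2 -5.37 ± 0.79 SE) and the phosphatase gene INPP4B was at -3.41 ± 1.79 against 5.12 ± 0.90 log2 CPM (SD, n = 3), both with adjusted p = 0.00391 and both lost without CD56dim library 4 (0.0692 each). FCGR3A differed by 2.94 ± 0.88 with adjusted p = 0.282. By edgeR 15 genes differed, 4 higher and 11 lower in CD56dim cells, but 0 of 11 were higher under RLE scaling. The count was 7 without CD56bright library 1, 3 without CD56dim library 2 and 0 without CD56dim library 4. With donor as a block it was 34, without the sparse libraries 61, with only these groups 0 and by limma-voom 54.

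In lung lymph node, FCGR3A was 73.8-fold higher in CD56dim cells (log2 6.21 ± 1.03 SE, adjusted p = 0.00807, but 0.141 without CD56bright library 4). CMKLR1 was at least 74-fold higher and at 0 in the 3 CD56bright libraries (adjusted p = 0.00605, but 0.106 without CD56bright library 4). By edgeR 28 genes differed, 18 higher and 10 lower in CD56dim cells, and all 11 called and named genes lost the call in at least 1 fit. The count was 52, 6 and 0 without CD56bright libraries 1, 2 and 4, and 52, 5 and 13 without CD56dim libraries 1, 2 and 4. With donor as a block it was 107, without the sparse libraries 209, with only these groups 9 and by limma-voom 63. NCAM1 was not called in any of the 5 tissues (log2 -0.58, -0.27, -0.68, -0.14 and -0.51 in blood, bone marrow, spleen, lung and lymph node). That a gene passed in one tissue and not in another is not a test of the difference, which is given further on.

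Lung CD56dim cells, set against blood CD56dim cells, had more transcript of NF-kB pathway and target genes. Immediate-early and heat shock lists also ranked higher, but lost the call with an estimated correlation. REL, an NF-kB subunit, was 10.2-fold higher (9.0 ± 0.50 against 5.70 ± 0.23 log2 CPM, SD, n = 3, adjusted p = 0.000404). RELB was 40.5-fold higher (log2 5.34 ± 0.82 SE), NFKB2 16.9-fold (4.08 ± 0.65) and CD83, an activation marker, 28.9-fold (4.85 ± 0.78). NR4A1, an orphan receptor induced by antigen-receptor signals, was 39.3-fold higher (5.30 ± 1.02) and HIF1A, the oxygen-sensing factor, 4.50-fold (2.17 ± 0.30, adjusted p = 0.000196). PTPN6, the phosphatase SHP-1, was 5.34-fold lower (-2.42 ± 0.50) and RGS19, a regulator of G-protein signals, 4.28-fold lower (-2.10 ± 0.36).

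By list, 14 of 19 NF-kB targets rose in lung CD56dim cells (18 when adjusted over the list alone, camera adjusted p = 6.52e-28, and 0.000121 with an estimated correlation). Of 16 heat shock genes 13 rose (15 when adjusted over the list alone, adjusted p = 4.17e-17, but adjusted p = 0.0619 with an estimated correlation), such as the chaperone DNAJB6, 3.19-fold higher (1.67 ± 0.30 SE). Of 22 immediate-early genes 4 rose (7 when adjusted over the list alone, adjusted p = 1.27e-08, but adjusted p = 0.124 with an estimated correlation). Of 19 cytokines and chemokines 6 rose (12 when adjusted over the list alone, adjusted p = 3.6e-07, and 0.0309 with an estimated correlation). Tissue residence genes ranked higher with 1 of 17 called (2 when adjusted over the list alone, adjusted p = 0.000153, and 0.00328 with an estimated correlation). Egress genes had 1 of 17 up (1 up and 1 down when adjusted over the list alone, adjusted p = 0.672). Of 20 CD56bright markers 3 rose (6 up and 1 down when adjusted over the list alone, adjusted p = 0.00877, but adjusted p = 0.336 with an estimated correlation). Of 21 glycolysis and hypoxia genes 3 rose (5 when adjusted over the list alone, adjusted p = 0.0163, but adjusted p = 0.338 with an estimated correlation), among them HIF1A and the enzyme PFKFB3, a driver of glycolysis, 8.41-fold higher. OASL, an interferon-induced gene, was 12.9-fold higher.

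Transcripts of lung epithelium moved with the same group. Of 15 epithelial, endothelial and stromal markers 7 were higher in lung than in blood CD56dim cells (13 when adjusted over the list alone, adjusted p = 5.65e-11, and 0.0319 with an estimated correlation). The surfactant genes SFTPC and SFTPA1 were at 7.44 ± 1.66 and 7.29 ± 2.13 log2 CPM in lung (SD, n = 3) and at 0 in all 3 blood libraries, a difference of at least 1429-fold and 1550-fold. SFTPB was at 8.02 ± 1.81 against -2.60 ± 0.72 log2 CPM (adjusted p = 7.99e-05). Monocyte and macrophage markers had 0 of 14 called (4 up when adjusted over the list alone, adjusted p = 0.512, but 0.00255 with donor as a block). Their list mean rose from blood to lung by 3.43 in donor 1 and 4.02 in donor 2, who gave both tissues.

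In total 352 genes differed between lung and blood in CD56dim cells by edgeR, 304 higher and 48 lower in lung. FCGR3A differed by -0.11 ± 0.82 and NCAM1 by -0.18 ± 0.53 on the log2 scale. The count was 97, 84 and 85 without blood libraries 1, 2 and 3, 209, 232 and 203 without lung libraries 1, 2 and 4, and 1082 without the sparse libraries, which are in neither group but enter the shared spread. Of 38 called and named genes 24 lost the call in at least 1 of the 6 fits, and 36 in at least 1 fit without a donor. The genes named here kept it in all 6, but only HIF1A and SFTPB kept it without any 1 donor.

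Lung lymph node CD56dim cells also had more transcript of NF-kB, immediate-early and heat shock genes than blood CD56dim cells, and of genes typical of CD56bright cells. IL7R was 34.8-fold higher than in blood (8.93 ± 1.53 against 4.06 ± 0.99 log2 CPM, SD, n = 3, adjusted p = 0.000479) and GPR183, the oxysterol receptor that positions lymphocytes, 14.7-fold higher (log2 3.88 ± 0.73 SE). CCR7 was at 5.48 ± 2.80 against -2.19 ± 2.03 log2 CPM (adjusted p = 0.0045) and IGFBP4 at 4.73 ± 2.34 against -3.91 ± 0.92 (adjusted p = 0.00182). CD83 was 47.9-fold higher (8.57 ± 0.06 against 2.99 ± 0.19), BIRC3, an inhibitor of apoptosis, 39.5-fold (5.30 ± 0.75 SE), and REL 9.60-fold (3.26 ± 0.50). NR4A1 was 187-fold higher (7.55 ± 1.13), AHR 12.5-fold (3.64 ± 0.59), AREG, amphiregulin, 9.83-fold (3.30 ± 0.60) and CXCR4, a retention receptor for CXCL12, 4.64-fold (2.21 ± 0.42).

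By list, 15 of 19 NF-kB targets rose in lymph node CD56dim cells (18 when adjusted over the list alone, camera adjusted p = 8.58e-29, and 0.000121 with an estimated correlation). Of 16 heat shock genes 15 rose (16 when adjusted over the list alone, adjusted p = 1.12e-23, and 0.0245 with an estimated correlation), with DNAJA1 12.7-fold higher and HSPE1 24.9-fold. Of 22 immediate-early genes 11 rose (17 when adjusted over the list alone, adjusted p = 4.67e-17, and 0.0238 with an estimated correlation). Of 19 cytokines and chemokines 8 rose (11 when adjusted over the list alone, adjusted p = 8.98e-10, and 0.00768 with an estimated correlation). Of 20 CD56bright markers 7 rose (11 when adjusted over the list alone, adjusted p = 5.47e-10, and 0.0207 with an estimated correlation). Library 1 stood apart, with a mean of 7.21 log2 CPM on this list against 5.39 and 5.43 in libraries 2 and 4. Of 17 tissue residence genes 4 rose (7 when adjusted over the list alone, adjusted p = 5.26e-05, and 0.00195 with an estimated correlation). Egress genes had 1 of 17 up (1 when adjusted over the list alone, adjusted p = 0.943).

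The monocyte and macrophage list and the erythroid and platelet list ranked lower in lymph node CD56dim cells. Few or no members were called, and both list calls were lost with an estimated correlation. Monocyte and macrophage markers had 2 of 14 down (2 when adjusted over the list alone, adjusted p = 0.000988, but adjusted p = 0.496 with an estimated correlation). Their list mean was 0.91, 0.82 and -3.34 log2 CPM in lymph node libraries 1, 2 and 4. It was 3.51, 1.49 and 2.80 in blood libraries 1, 2 and 3, and donor 4 gave no blood. Erythroid and platelet markers had 0 of 8 called over all genes and 8 lower when adjusted over the list alone (adjusted p = 7.06e-05, but adjusted p = 0.225 with an estimated correlation). In total 409 genes differed by edgeR, 348 higher and 61 lower in lymph node. FCGR3A differed by -0.60 ± 0.82 and NCAM1 by -0.20 ± 0.53. The count was 121, 102 and 67 without blood libraries 1, 2 and 3, 218 without lymph node library 1, and 1147 without the sparse libraries. Of 39 called and named genes 20 lost the call in at least 1 fit, and 35 in at least 1 fit without a donor. Those named here kept it in all 6, but only IL7R, AREG, BIRC3 and DNAJA1 kept it without any 1 donor.

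**Figure D3:**
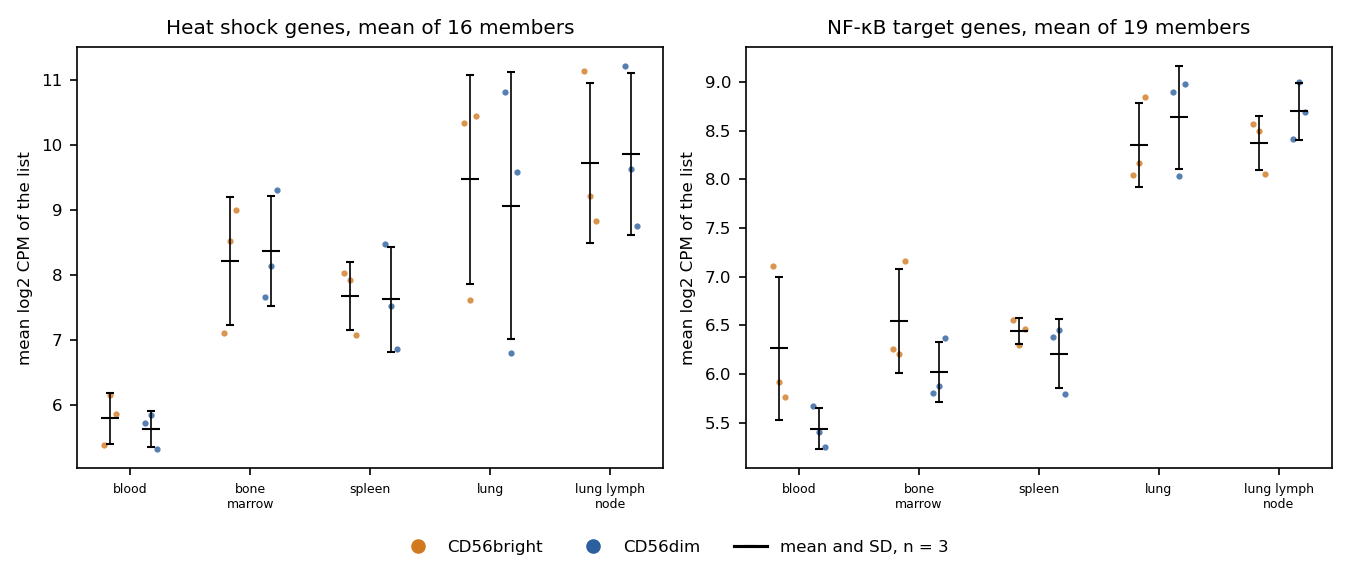
Mean log2 CPM (y axis) of 16 heat shock genes and of 19 NF-kB targets in each library (points), by tissue (x axis) and subset (colour), with mean and SD of 3 libraries (bars). Heat shock means were at most 6.16 in the 6 blood libraries and at least 6.81 in the other 24, and NF-kB means at least 8.03 in lung and lymph node and at most 7.16 elsewhere.

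**Figure D4:**
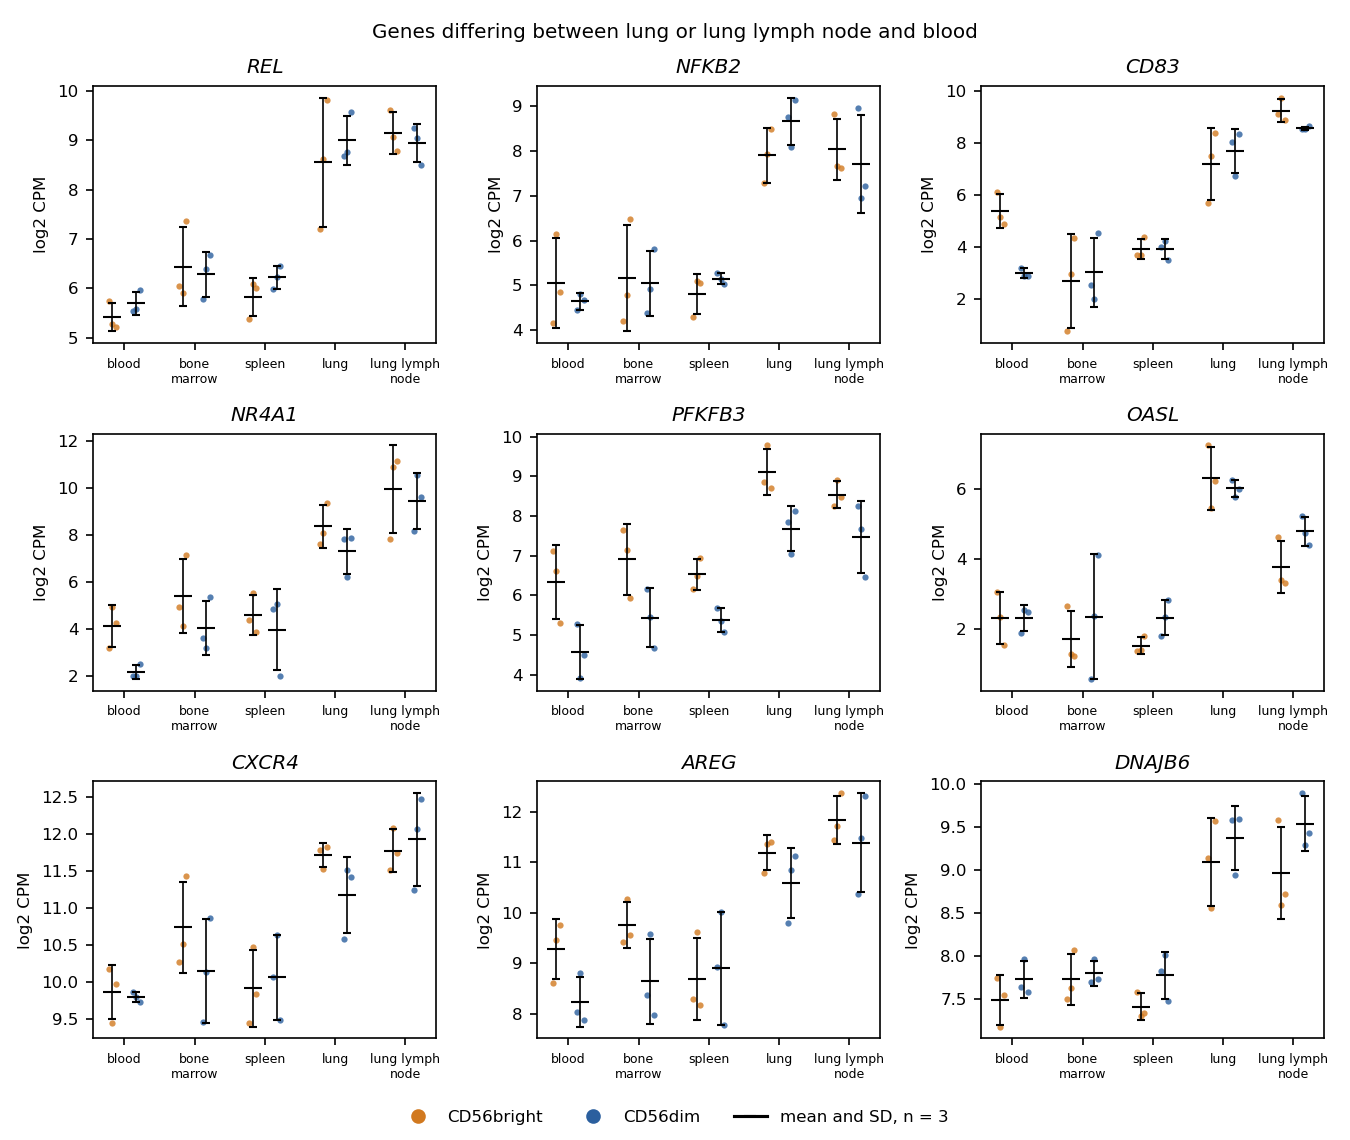
Expression of 9 genes (panels; y axis log2 CPM) by tissue (x axis) and subset (colour); points are libraries and bars mean and SD of 3. REL in CD56dim cells was at 5.70 ± 0.23 in blood and 9.0 ± 0.50 in lung, and CD83 at 2.99 ± 0.19 in blood and 8.57 ± 0.06 in lymph node.

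Bone marrow and spleen CD56dim cells had 0 and 1 genes called against blood CD56dim cells, while the heat shock list ranked higher in both. Its mean was 8.38 ± 0.84 log2 CPM in bone marrow and 7.63 ± 0.81 in spleen against 5.63 ± 0.28 in blood (SD, n = 3). In bone marrow 0 of 16 heat shock genes were called over all genes and 6 when adjusted over the list alone (camera adjusted p = 5.69e-32, and 0.0085 with an estimated correlation). In spleen 0 were called, and 4 when adjusted over the list alone (adjusted p = 6.57e-17, but adjusted p = 0.0601 with an estimated correlation). Cytokines and chemokines ranked higher with 0 of 19 called in bone marrow (0 when adjusted over the list alone, adjusted p = 1.17e-09, and 0.0085 with an estimated correlation). The same held in spleen (0 when adjusted over the list alone, adjusted p = 4.81e-08, and 0.0181 with an estimated correlation).

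NF-kB targets ranked higher with 0 of 19 called in bone marrow (adjusted p = 0.000327, but adjusted p = 0.131 with an estimated correlation) and in spleen (adjusted p = 1.23e-06, and 0.041 with an estimated correlation). Immediate-early genes ranked higher with 0 of 22 called in bone marrow (adjusted p = 4.07e-09, but adjusted p = 0.116 with an estimated correlation). The same held in spleen (3 when adjusted over the list alone, adjusted p = 1.5e-09, but adjusted p = 0.108 with an estimated correlation). Tissue residence genes ranked higher with 0 of 17 called in bone marrow (1 when adjusted over the list alone, adjusted p = 0.036, but adjusted p = 0.0752 with an estimated correlation). In spleen they did the same (1 when adjusted over the list alone, adjusted p = 0.0157, and 0.041 with an estimated correlation). Egress genes had 0 of 17 called in bone marrow (adjusted p = 0.897) and in spleen (adjusted p = 0.0446, but adjusted p = 0.305 with an estimated correlation). With donor as a block the NF-kB, immediate-early and residence lists in bone marrow had adjusted p = 0.285, 0.123 and 0.07.

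Lists of other cell types' markers also differed in rank in these groups, with 0 members called. Granulocyte and progenitor markers ranked higher in bone marrow (0 of 11 called, 4 higher when adjusted over the list alone, adjusted p = 2.62e-06, but adjusted p = 0.0883 with an estimated correlation). B cell markers ranked higher in spleen (0 of 9 called, 5 higher when adjusted over the list alone, adjusted p = 3.79e-10, and 0.0309 with an estimated correlation). So did plasma cell markers (0 of 5 called, adjusted p = 8.89e-05, and 0.00973 with an estimated correlation). Erythroid and platelet markers ranked lower in bone marrow (0 of 8 called, 4 lower when adjusted over the list alone, adjusted p = 3.78e-06, but adjusted p = 0.133 with an estimated correlation and 0.0954 with donor as a block). They did so in spleen too (0 of 8 called, 5 lower when adjusted over the list alone, adjusted p = 1.2e-07, but adjusted p = 0.0919 with an estimated correlation).

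By edgeR 0 genes differed between bone marrow and blood in CD56dim cells, with 162 at an unadjusted p under 0.05. The count was 2 without bone marrow library 1, 4 without the sparse libraries, 35 by DESeq2, 22 by limma-trend on the authors' values and 48 by limma-voom. Between spleen and blood 1 gene differed, the histone gene HIST1H2AE, 18.4-fold higher in spleen (log2 4.20 ± 0.66 SE, adjusted p = 0.0145). It lost the call without any of blood libraries 1, 2 and 3 or spleen libraries 1 and 3, when 0 genes were called (up to adjusted p = 0.377 without blood library 3). The other counts for spleen were 185 at an unadjusted p under 0.05, 4 without the sparse libraries, 47 by DESeq2, 20 by limma-trend and 355 by limma-voom. FCGR3A differed from blood by 0.44 ± 0.82 in bone marrow and 0.23 ± 0.82 in spleen, and NCAM1 by 0.17 ± 0.53 and -0.27 ± 0.53. Over all 5 tissues 686 genes differed in CD56dim cells in the test with 4 degrees of freedom, and 1596 without the sparse libraries.

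In CD56bright cells the blood group held 2 sparse libraries, so the genes set out here are mainly those also called against spleen, with the log2 change from spleen given. Lung CD56bright cells had more REL than blood (11.2-fold, log2 3.49 ± 0.50 SE, adjusted p = 9.2e-05; 3.06 from spleen) and more NFKB2 (6.51-fold, 2.70 ± 0.61; 3.13 from spleen). LDHA and PGK1, glycolytic enzymes, were 3.67-fold (1.88 ± 0.33; 2.19 from spleen) and 4.72-fold higher (2.24 ± 0.42; 2.64 from spleen). OASL was 16.7-fold higher (4.06 ± 0.73; 4.97 from spleen) and the chaperone DNAJA1 9.03-fold (3.18 ± 0.56; 2.34 from spleen). Against blood alone, RGS1, a marker of tissue-resident lymphocytes, was 14.2-fold higher (3.83 ± 0.79). It kept the call when any 1 library was left out, but not against spleen (1.65).

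By list, 7 of 17 residence genes rose in lung CD56bright cells (12 when adjusted over the list alone, camera adjusted p = 0.000397, and 0.00545 with an estimated correlation). Of 16 heat shock genes 12 rose (14 when adjusted over the list alone, adjusted p = 1.8e-06, but adjusted p = 0.338 with an estimated correlation). Of 19 NF-kB targets 10 rose (12 when adjusted over the list alone, adjusted p = 0.00055, but adjusted p = 0.14 with an estimated correlation). Cytokines and chemokines had 11 up and 2 down of 19 (13 and 2 when adjusted over the list alone, adjusted p = 0.00298, but adjusted p = 0.193 with an estimated correlation). Egress genes had 3 of 17 down (4 when adjusted over the list alone, adjusted p = 0.00402, but adjusted p = 0.12 with an estimated correlation). Immediate-early genes (4 of 22 up, 7 when adjusted over the list alone, adjusted p = 0.0667), glycolysis and hypoxia genes (4 of 21 up, 4 when adjusted over the list alone, adjusted p = 0.345) and CD56bright markers (2 up and 4 down of 20, the same when adjusted over the list alone, adjusted p = 0.0675) did not pass camera. Epithelial, endothelial and stromal markers moved with this group too, with 10 of 15 up (11 when adjusted over the list alone, adjusted p = 0.000589, but adjusted p = 0.323 with an estimated correlation). SFTPB was at 8.50 ± 1.87 log2 CPM in lung against -3.50 ± 0.84 in blood (SD, n = 3).

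Between lung and blood 1987 genes differed in CD56bright cells by edgeR, 1310 higher and 677 lower in lung. The count was 3419 without blood library 3; it was 1664 without the sparse libraries, of which 866 were in both sets, 658 against spleen, 11 by limma-voom and 0 when only these groups were fitted. Of 42 called and named genes 9 lost the call in at least 1 left-out library and 30 in at least 1 left-out donor. FCGR3A was among the 9, 2.55 ± 0.87 higher in lung on the log2 scale with adjusted p = 0.045, which was 0.109 and 0.0966 without blood libraries 2 and 3, 0.0536 and 0.325 without lung libraries 2 and 4, and 0.166 with donor as a block.

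Lung lymph node CD56bright cells had 13.6-fold more REL than blood (log2 3.76 ± 0.51 SE, adjusted p = 8.22e-05; 3.34 from spleen), 14-fold more CD83 (3.81 ± 0.74; 5.34 from spleen) and 10.9-fold more TNFAIP3, an inhibitor of NF-kB signalling (3.45 ± 0.73; 5.51 from spleen). NR4A1 was 75.4-fold higher (6.24 ± 1.07; 5.74 from spleen) and DNAJA1 12.1-fold (3.6 ± 0.57; 2.77 from spleen). AHR was 7.84-fold higher (2.97 ± 0.57; 3.11 from spleen), GPR183 8.18-fold (3.03 ± 0.70; 4.05 from spleen) and AREG 5.81-fold (2.54 ± 0.58; 3.04 from spleen), but these last 3 lost the call without the sparse libraries. ITGB2, the beta-2 integrin chain, was 3.63-fold lower (-1.86 ± 0.38; -1.56 from spleen). Against blood alone TBX21, the transcription factor T-bet, was 6.21-fold lower (-2.63 ± 0.54), a call lost without the sparse libraries.

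By list, 9 of 19 NF-kB targets rose in lymph node CD56bright cells (12 when adjusted over the list alone, camera adjusted p = 3.06e-05, but adjusted p = 0.0745 with an estimated correlation). So did 13 of 16 heat shock genes (15 when adjusted over the list alone, adjusted p = 2.58e-08, but adjusted p = 0.252 with an estimated correlation). Of 17 residence genes 5 rose (7 when adjusted over the list alone, adjusted p = 0.0172, and 0.0454 with an estimated correlation). Immediate-early genes had 6 of 22 up (7 when adjusted over the list alone, adjusted p = 0.0127, but adjusted p = 0.577 with an estimated correlation and 0.17 with donor as a block). Mature CD56dim markers had 4 of 16 down (1 up and 5 down when adjusted over the list alone, adjusted p = 0.00046, but adjusted p = 0.273 with an estimated correlation). Markers of other innate lymphoid cells had 3 of 9 up (4 when adjusted over the list alone, adjusted p = 0.0226, but adjusted p = 0.0671 with an estimated correlation). Cytokines and chemokines (5 of 19 up, 8 up and 1 down when adjusted over the list alone, adjusted p = 0.0675) and egress genes (2 of 17 down, 2 when adjusted over the list alone, adjusted p = 0.0613) did not pass camera.

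Some markers of blood myeloid cells were lower in the same lymph node group, but the list calls were lost with an estimated correlation. The calgranulins S100A9 and S100A8, abundant in monocytes and neutrophils, were at 10.98 ± 0.91 and 10.93 ± 1.23 log2 CPM in blood CD56bright libraries and 2.06 ± 2.08 and 2.21 ± 2.07 in lymph node (SD, n = 3, adjusted p = 0.00878 and 0.0103). Monocyte and macrophage markers had 4 of 14 down (1 up and 7 down when adjusted over the list alone, adjusted p = 0.0022, but adjusted p = 0.532 with an estimated correlation). In donors 1 and 2, who gave both, their list mean was 0.33 and 2.12 log2 CPM in blood and 0.28 and 1.77 in lymph node. Granulocyte and progenitor markers had 1 up and 3 down of 11 (1 and 5 when adjusted over the list alone, adjusted p = 0.00184, but adjusted p = 0.273 with an estimated correlation). Erythroid and platelet markers had 3 of 8 down (7 when adjusted over the list alone, adjusted p = 0.0388, but adjusted p = 0.578 with an estimated correlation and 0.197 with donor as a block). By edgeR 1344 genes differed, 929 higher and 415 lower in lymph node. The count was 2930 without blood library 3 and 882 without lymph node library 2. It was 1099 without the sparse libraries, of which 496 were in both sets, 341 against spleen, and 0 by limma-voom or when only these groups were fitted. FCGR3A differed by -1.22 ± 0.84 (adjusted p = 0.384).

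Spleen CD56bright cells had 9.74-fold less GNLY, the granule protein granulysin, than blood (10.02 ± 0.43 against 13.33 ± 0.21 log2 CPM, SD, n = 3, adjusted p = 0.0016), 2.95-fold more CD96, an adhesion and inhibitory receptor (log2 1.56 ± 0.30 SE), and 19.7-fold less EPHA4, an ephrin receptor (-4.30 ± 0.69). These calls held when any 1 library was left out, but not without donor 2 (adjusted p = 0.0799, 0.0619 and 0.0544). They also held without the sparse libraries, but that fit has 1 blood CD56bright library and is weak evidence. CD244 (4.35-fold, 2.12 ± 0.42) and CXCR6 (16-fold, 4.00 ± 0.94) were higher than in blood but not called in that fit. LIF, a cytokine of the interleukin-6 family, was at least 153-fold higher in spleen, at least 222-fold in bone marrow and at least 112-fold in lymph node, with 0 counts in the 3 blood CD56bright libraries. In bone marrow CD244 was 3.85-fold higher than in blood (1.95 ± 0.42, adjusted p = 0.00668), PRDM1, the factor BLIMP-1, 3.87-fold (1.95 ± 0.46) and DUSP6, a phosphatase of the ERK pathway, 10.8-fold (3.43 ± 0.73). All 3 lost the call without the sparse libraries, as did most of the named bone marrow and spleen results, which can reflect the lost power of a fit with 1 blood library. FCGR3A differed from blood by 1.89 ± 0.85 in bone marrow (adjusted p = 0.201) and by 2.92 ± 0.88 in spleen. Its adjusted p in spleen was 0.0416, but 0.0514, 0.0878 and 0.0737 without blood libraries 1, 2 and 3, 0.541 without spleen library 2 and 0.0528 with donor as a block.

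By list, egress genes fell in spleen CD56bright cells, 4 of 17 (7 when adjusted over the list alone, camera adjusted p = 0.00024, and 0.0485 with an estimated correlation). They ranked lower in bone marrow with 0 of 17 called (adjusted p = 0.0071, but adjusted p = 0.14 with an estimated correlation). Residence genes had 4 of 17 up in bone marrow (5 when adjusted over the list alone, adjusted p = 0.0354, but adjusted p = 0.0745 with an estimated correlation). In spleen 4 were up (5 up and 1 down when adjusted over the list alone, adjusted p = 0.0667, and 0.0304 with donor as a block). Heat shock genes had 4 of 16 up in bone marrow (5 when adjusted over the list alone, adjusted p = 0.00153, but adjusted p = 0.566 with an estimated correlation). In spleen 3 were up (4 when adjusted over the list alone, adjusted p = 0.166). Cytokines and chemokines had 3 of 19 up in bone marrow (7 up and 1 down when adjusted over the list alone, adjusted p = 0.0309, but adjusted p = 0.362 with an estimated correlation and 0.0796 with donor as a block). In spleen 7 were up (7 up and 2 down when adjusted over the list alone, adjusted p = 0.0676). Immediate-early genes (1 of 22 up in each, adjusted p = 0.345 and 0.751) and NF-kB targets (1 and 2 of 19 up, adjusted p = 0.532 and 0.189) did not pass camera in bone marrow or spleen.

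Between bone marrow and blood 705 genes differed in CD56bright cells by edgeR, 532 higher in bone marrow, and between spleen and blood 950, of which 633 were higher in spleen. Without blood library 3 the counts were 2182 and 2446, and without spleen libraries 1, 2 and 3 the spleen count was 475, 452 and 527. Without the sparse libraries they were 520 and 966, of which 167 and 359 were in both sets. Both were 0 by limma-voom and when only the groups compared were fitted, and the bone marrow count was 0 against spleen. Over the 5 tissues 2024 genes differed in CD56bright cells in the test with 4 degrees of freedom, and 3379 without blood library 3.

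The subset difference depended on tissue for 28 genes in the test with 4 degrees of freedom by edgeR, such as the cholesterol synthesis enzyme gene NSDHL (adjusted p = 0.000116) and the kinase gene CDK8 (adjusted p = 0.00216). NSDHL was at -3.98 ± 0.81 log2 CPM in blood CD56bright cells and 3.74 ± 0.22 in blood CD56dim cells, and CDK8 at -2.62 ± 0.87 and 3.12 ± 0.26 (SD, n = 3). The other 8 named genes also had their lowest group mean in blood CD56bright cells, 2 of whose 3 libraries are sparse. All 10 named genes lost the call without at least 1 donor, and 0 genes were called without donor 2. The step from blood to spleen differed between the subsets for CD244 (log2 -0.35 in CD56dim and 2.12 in CD56bright cells, difference -2.47 ± 0.58 SE, adjusted p = 0.0342), GNLY (0.17 and -3.28, difference 3.45 ± 0.79, adjusted p = 0.0324) and CD96 (-0.21 and 1.56, difference -1.77 ± 0.41, adjusted p = 0.0342). The step from blood to lymph node differed for IGFBP4 (10.26 in CD56dim and 0.55 in CD56bright cells, difference 9.71 ± 2.05, adjusted p = 0.0205). Against blood the single tests called 76 genes for bone marrow, 120 for spleen, 90 for lung and 93 for lymph node. The count of 28 was 47, 50 and 668 without blood CD56bright libraries 1, 2 and 3, 52 and 87 without bone marrow CD56bright libraries 2 and 4, and 96 without the 3 sparse libraries, of which 16 were in both sets. It was 18 without blood CD56dim library 1, bone marrow CD56dim library 4, spleen CD56bright library 1 or 2, lung CD56dim library 2 or lung CD56bright library 4, and 17 without blood CD56dim library 3, spleen CD56bright library 3, or spleen CD56dim library 1 or 2.

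**Figure D5:**
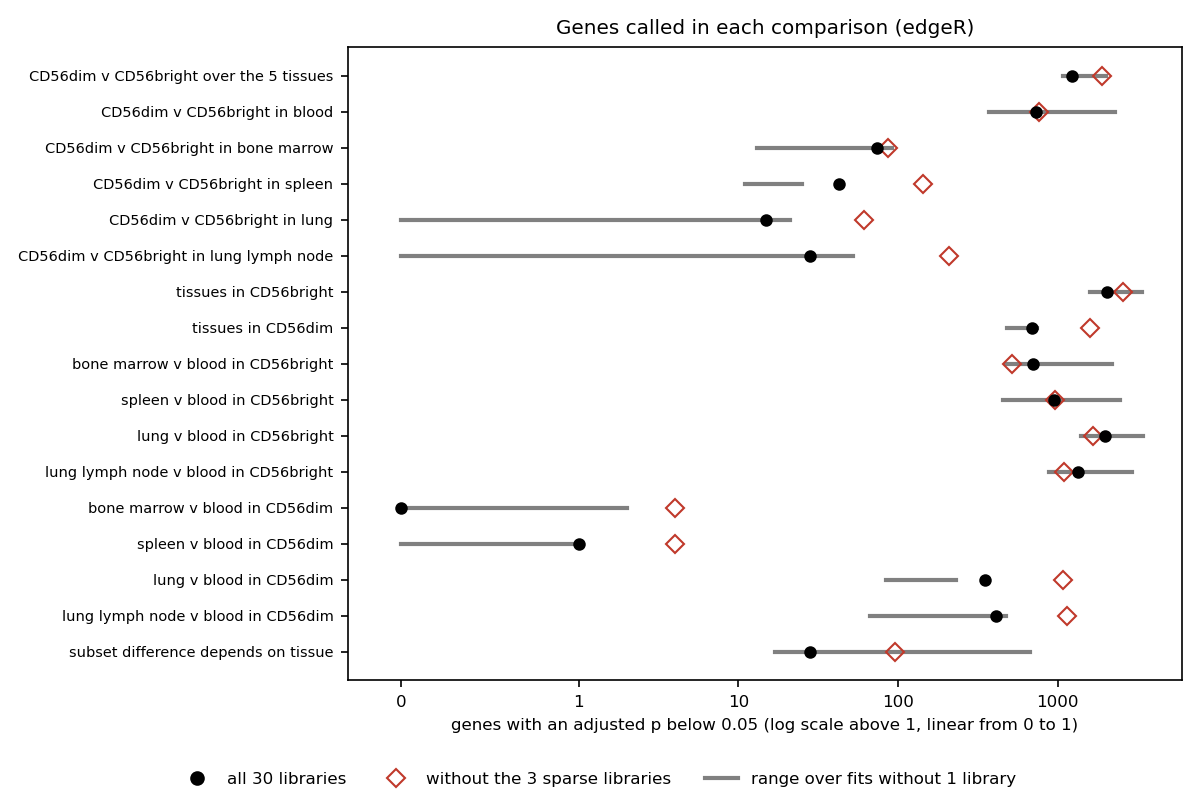
Number of genes with an adjusted p under 0.05 (x axis, logarithmic above 1 and linear from 0 to 1) in the 17 comparisons (y axis): all 30 libraries (black dots), without the 3 sparse libraries (open red diamonds) and the range over fits without 1 library (grey lines). The subset difference over tissues ranges from 1075 to 2008, and its dependence on tissue from 17 to 668.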

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

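Of the tests in this part, those of digestion, of donors and of monocyte RNA were chosen only after the result was seen.

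Many genes were higher in each tissue than in blood CD56bright cells, and 2 of the 3 blood libraries had many genes at 0. Lower depth does not account for the zeros, since the CD56bright libraries outside the 3 sparse ones were thinned to the total of blood library 2. They would have at most 693 genes at 0 (blood library 3, and the lowest was 34), against 1787 and 1729 found. The genes called higher without blood library 3 lay above that library by a median log2 difference of 0.33 in bone marrow (1683 genes, quartiles -0.74 and 1.65). Their difference from libraries 1 and 2 was 4.90. Since the genes were chosen for being higher than libraries 1 and 2, that value is set by the choice. A smaller difference from library 3 is expected by selection alone, so missing transcripts are only a candidate explanation of many bone marrow calls. In spleen the median was 0.58 against 5.79 (1749 genes), in lung 0.95 against 5.32 (2372 genes) and in lymph node 0.76 against 5.43 (2106 genes), with quartiles on both sides of 0, so missing transcripts and a tissue difference cannot be told apart there with 1 fuller blood library. A tissue difference stays open and untested.

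The heat shock list ranked higher in all 4 tissues than in blood CD56dim cells, but 0 of 16 members were called in bone marrow and spleen, and the list call was lost with an estimated correlation in spleen (adjusted p = 0.0601) and lung (0.0619). List medians against blood were 1.8 on the log2 scale in bone marrow, 0.87 in spleen, 3.16 in lung and 4.17 in lymph node. Digestion, which the labels state for spleen and lung, cannot be excluded as the cause. The list mean of bone marrow and lymph node minus that of spleen and lung was -0.21 in donor 1, 1.72 in donor 2 and -0.56 in donor 4 (lung only), and whether bone marrow and lymph node were digested was not specified. A difference in donors is argued against, since within donors 1 and 2, who gave both blood and tissue, the lowest list median of a tissue against blood was 1.07, in spleen (lower quartile 0.61), and the others were 1.12, 2.95 and 4.37 in bone marrow, lung and lymph node. Other handling, such as the unstated processing of bone marrow and lymph node or the time until sorting, was confounded with tissue and stays open. A biological difference between tissues stays open too, as untested.

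NF-kB targets were higher in lung and lymph node than in blood CD56dim cells, by 3.23 on the log2 scale for the list mean. Whether a response shared with the heat shock genes is the whole cause cannot be told. After removal of the within-tissue slope on the heat shock mean (0.18 ± 0.08 SE), 78.7% of the difference was left (2.54 ± 0.37 SE). The slope came from few libraries within tissues, where a noisy heat shock mean makes it too shallow. It was carried over a heat shock difference of 3.84 between tissues as if linear, so a large remainder can arise even under a shared response. RNA of monocytes and macrophages is argued against in lymph node, where their markers had a median log2 difference of -3.48 from blood (quartiles -5.56 and -1.38) and S100A9 was at 1.23 ± 3.30 log2 CPM against 8.59 ± 1.78 in blood (SD, n = 3). These pooled values include donor 4, whose lymph node library had a list mean of -3.34 log2 CPM and who gave no blood. Within donors 1 and 2, who gave both, the list mean of these markers was also lower than in blood (-2.60 and -0.67). In lung the pooled median was -0.04 with quartiles of -1.08 and 4.44, but within donors 1 and 2 the list mean rose by 3.43 and 4.02, so such RNA cannot be excluded there, although cells were sorted on CD56. In lung library 4 the monocyte list mean was -0.71 and the NF-kB mean 8.98 log2 CPM, but a single library decides nothing. Activation during handling and a tissue difference stay open and untested, and the pattern is a hypothesis.

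Each count of genes was set against other splits of the same libraries. In the tests over several tissues, the real split called more genes than any drawn split. For the subset difference over tissues it called 1232 genes (highest of the other 49 splits 61, and 18 among 30 draws within donors). For tissues in CD56bright cells it called 2024 (highest other 690, and 1325 among 30 draws within donors). For tissues in CD56dim cells it called 686 (highest other 163, and 51 within donors). For the dependence on tissue it called 28 (highest other 19, and 0 within donors). In each of these the real split was the only 1 of 50 with as many genes. This argues against chance for the first 3 counts. Since a drawn split called up to 1325 genes, the size of a count does not measure a tissue difference. For the dependence, 28 lay close to 19 and 0 genes were called without donor 2, so chance is not excluded. The 10 splits of 3 and 3 libraries are too few for a share under 0.05. Their real and highest other counts were 736 and 4 for the subsets in blood, 74 and 0 in bone marrow, 43 and 0 in spleen, 15 and 1 in lung, and 28 and 136 in lymph node. For CD56bright cells they were 705 and 930 in bone marrow against blood, 950 and 0 in spleen, 1987 and 20 in lung and 1344 and 71 in lymph node. For CD56dim cells they were 0 and 0 in bone marrow (10 of 10 splits gave as many), 1 and 0 in spleen, 352 and 0 in lung, and 409 and 0 in lymph node. For 2 comparisons, the subsets in lymph node and bone marrow against blood in CD56bright cells, 2 of 10 splits gave as many genes. The split with 930 genes was the one that set the 3 sparse libraries apart. The split with 136 genes set lymph node CD56bright library 1 with CD56dim libraries 1 and 4, which points to a structure of the libraries other than subset; with donor as a block the real count there was 107.

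The subset difference varied over the 5 tissues, by the test of the interaction, for NSDHL (adjusted p = 0.000116), SERAC1 (0.00133), CAMKMT (0.00133), FLVCR1 (0.00136), CDK8 (0.00216), VIPAS39 (0.00301), ITGA3 (0.00445), and KBTBD7, LXN and MICA (0.00573 each). The step from blood to bone marrow differed between the subsets for TIRAP (adjusted p = 0.00171), DKK3 (0.0493), GPR55 (0.0315), MAD2L1 (0.0012) and BORA (0.00265). The step to spleen differed for TIRAP (0.000703), CD244 (0.0342), GNLY (0.0324), GPR55 (0.0324), CCRL2 (0.0342), EPHA4 (0.015) and CD96 (0.0342). The step to lung differed for TIRAP (0.001), IGFBP4 (0.0108, difference 10.68 ± 2.08 SE on the log2 scale) and PERP (0.0258), and the step to lymph node for EHD3 (0.0222), TIRAP (0.000888), IGFBP4 (0.0205) and AVPI1 (0.00474). ITGA3, TIRAP, GPR55, MAD2L1, BORA, CCRL2, PERP, EHD3 and AVPI1 were at 0 in all 3 blood CD56bright libraries.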

How the results depend on the processing

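The alternatives without the 3 sparse libraries, with spleen as reference, with the symbols at 0 in donor 4 kept and with limma-voom were chosen only after seeing the data. Under RLE scaling and with the symbols kept, all 17 counts stayed within 1.5 times, and the filter alternative was void. Values are numbers of genes called, in the order subsets over tissues, subsets in blood, bone marrow, spleen, lung and lymph node, tissues in CD56bright and in CD56dim, then bone marrow, spleen, lung and lymph node against blood in CD56bright and in CD56dim, and the dependence on tissue, with counts within 1.5 times left out. The cause was not tested for any of these changes. The majority direction of the subset calls turned over tissues with RLE (571 of 1255 higher in CD56dim), DESeq2 (781 of 1803) and limma-trend (1377 of 2873), in blood with limma-voom (5 of 43), and in bone marrow (274 of 532) and lymph node (261 of 597) with limma-trend.

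With DESeq2 the counts were higher: 1600, 299, 215, 136 and 250 for the subsets in blood, bone marrow, spleen, lung and lymph node, 3343 and 1225 for tissues in CD56bright and CD56dim, 1501, 1763 and 2260 for bone marrow, spleen and lymph node in CD56bright, 35, 47, 873 and 944 for the 4 tissues in CD56dim, and 275 for the dependence. With limma-trend on the authors' normalized values, from which donor differences are nearly absent, all 17 were higher: 2873, 2823, 532, 453, 419, 597, 6406, 2366, 3037, 3528, 5024, 4211, 22, 20, 1967, 1601 and 505. With donor as a block they were 1168, 149, 104, 34 and 107 for the subsets within tissues, 1441 for spleen in CD56bright, 1 and 621 for bone marrow and lung in CD56dim, and 51 for the dependence.

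With only the groups compared they were 3, 26, 475, 0 and 9 for the subsets in blood, bone marrow, spleen, lung and lymph node, 429 and 1499 for tissues in CD56bright and CD56dim, 0 for each of the 4 tissues in CD56bright, and 11 and 1246 for spleen and lung in CD56dim. With limma-voom they were 43, 270, 1310, 54 and 63 for the subsets within tissues, 26 and 3110 for tissues, 0, 0, 11 and 0 for the 4 tissues in CD56bright, 48, 355, 2478 and 804 in CD56dim, and 0 for the dependence. Without the sparse libraries they were 1905 for the subsets over tissues, 144, 61 and 209 in spleen, lung and lymph node, 1596 for tissues in CD56dim, 4, 4, 1082 and 1147 for the 4 tissues in CD56dim, and 96 for the dependence. With spleen as reference they were 0, 658 and 341 for bone marrow, lung and lymph node in CD56bright and 164 for lymph node in CD56dim.

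Leaving out 1 library or 1 donor at a time gave these lowest and highest counts: 472 and 2008 for the subsets over tissues; 67 and 2288 in blood, 2 and 92 in bone marrow, 0 and 51 in spleen, 0 and 21 in lung, and 0 and 109 in lymph node. Tissues gave 247 and 3379 in CD56bright and 111 and 740 in CD56dim. For bone marrow, spleen, lung and lymph node against blood they were 85 and 2182, 87 and 2446, 347 and 3419, and 137 and 2930 in CD56bright, and 0 and 2, 0 and 1, 12 and 327, and 29 and 473 in CD56dim. The dependence on tissue gave 0 and 668. The lowest count was without donor 2 for the subsets over tissues, for tissues in either subset and for the dependence on tissue. Where a group kept 1 or 2 libraries, their spread was assumed to be that of the other groups.

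Of 352 named gene results 329 were called, of which 130 lost the call without at least 1 library and 241 without at least 1 donor. With spleen as reference 11 named results reversed. In bone marrow CD56bright cells these were MAD2L1 (-0.28 on the log2 scale), CD96 (-0.35), CD244 (-0.17), TOX (-0.04), CCL4 (-0.41) and GNLY (1.38); in lung CD56bright cells CXCR6 (-1.02), DUSP6 (-0.09) and FCGR3A (-0.37); in lymph node CD56bright cells LIF (-0.15); and in lung CD56dim cells HSPA1B (-0.40). Other settings ended 169 calls (limma-voom), 161 (only the groups compared), 82 besides the 11 reversed, which were not called there either (spleen as reference), 74 (without the sparse libraries), 13 (symbols kept), 4 (donor block), 3 (RLE) and 3 (authors' values). Of 91 list results 35 lost the call with an estimated correlation, 24 with fry and 7 with donor as a block. The median, mean and test of a list differed in sign for chemokine receptors between the subsets over tissues, for NF-kB targets in bone marrow and immediate-early genes in spleen CD56bright cells, and for egress genes in bone marrow and lung CD56dim cells, none of them called. Depth limits genes near 0: the floor of 3 counts was a mean of 0.24 CPM over the 3 blood CD56bright libraries.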

Other observations

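The list means in this part were chosen only after the results were seen, and no test was run on the means themselves. The 350 camera tests included these lists for the subsets within each tissue, but those results are not given here.

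In bone marrow, spleen, lung and lymph node, tissue residence genes had a higher mean in CD56bright than in CD56dim libraries. The mean of the 17 tissue residence genes was 3.19 ± 0.65 log2 CPM in blood CD56bright and 3.33 ± 0.07 in blood CD56dim libraries (SD, n = 3). The sparse blood CD56bright libraries 1 and 2 were at 3.22 and 2.53, and the fuller library 3 at 3.82, above the 3 CD56dim libraries (3.25 to 3.39), so blood is not set against the tissues here. The mean was 5.21 ± 0.61 and 3.59 ± 0.37 in bone marrow, 5.64 ± 0.21 and 3.76 ± 0.50 in spleen, 6.99 ± 0.30 and 4.75 ± 0.33 in lung, and 5.87 ± 0.38 and 4.45 ± 0.69 in lymph node. The lowest CD56bright library of each of these 4 tissues lay above the highest CD56dim library of the same tissue, a separation that chance gives in 10% of 3 by 3 comparisons.

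The marker list of mature CD56dim cells had a mean of 8.13 ± 0.20 log2 CPM in blood CD56dim libraries, 7.73 ± 0.21 in lung and 6.87 ± 1.32 in lymph node (SD, n = 3). In the same lymph node libraries the CD56bright marker list had a mean of 6.01 ± 1.04, against 3.92 ± 0.28 in blood CD56dim and 7.83 ± 0.35 in lymph node CD56bright libraries. Lymph node CD56dim library 1 stood apart, at 7.21 on the CD56bright list and 5.38 on the mature list, against 5.39 and 7.88 in library 2 and 5.43 and 7.35 in library 4. It lay above the blood CD56bright libraries (7.03 to 7.11) on the CD56bright list, while libraries 2 and 4 lay between the libraries of the blood subsets on both lists. On the mature list lung CD56bright library 4 was the highest CD56bright library, at 6.18, with 7.09 on the CD56bright list. Lung CD56bright libraries 1 and 2 were at 2.46 and 4.47 on the mature list. Whether such profiles are a state of single cells or a mixture of sorted cells cannot be read from bulk RNA. Monocyte and macrophage markers varied most in lung, with means of 3.42 ± 5.14 in CD56bright and 3.91 ± 4.07 in CD56dim libraries. Library 4 stood apart there, at -2.5 in CD56bright and -0.71 in CD56dim. Libraries 1 and 2 were at 5.99 and 6.77 in CD56bright and at 6.94 and 5.51 in CD56dim. Donor 4 was also low in bone marrow (0.05 in CD56bright and -1.03 in CD56dim) and in lymph node (-2.61 and -3.34). Each of its libraries lay below every library of the other donors, so the low values went with donor 4 and not with lung alone.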
